A study of Macaca mulatta with 20 samples.

How the data were processed

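Messenger RNA was measured in 20 corpora lutea of rhesus macaques with Affymetrix rhesus arrays, with biotin-labelled cRNA made from RNA extracted with TRIzol. Per the labels there were 5 groups of 4: untreated on luteal day 10, and hCG from luteal day 9 with collection on days 10, 12, 15 and 18. The replicate numbers do not state animals or batches, and no scan date was used.

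The deposited values are one signal per probe set and array, a linear intensity that the authors made with the Affymetrix GCOS software, whose version and scaling target the labels do not give. Tested on the table, every array has a 2% trimmed mean of 200.01 or 200.02, so the authors scaled each array to a common target. No step that makes the distributions of the arrays alike is visible, and no detection calls or raw images were used here. Arrays have no read depth, and their number limits the precision.

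All 52865 probe sets were read and 158 array control probe sets were left out, which left 52707. Of these, 24956 carry 1 gene symbol (14132 symbols), 361 carry several and 27390 none. The symbols came from the platform annotation, and positions in a genome build were not used. Signals were analysed as the log2 of the value + 16, with no further scaling and no filter on dim probe sets. One linear model with a mean per group was fitted to all 20 arrays with limma (version 3.58.1) in R (version 4.3.3), with eBayes moderation and contrasts. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The tests were the moderated F over the 4 contrasts against untreated day 10, these 4 contrasts and the 3 steps between collection days. Errors of log2 changes are standard errors, and those of signals are standard deviations over 4 arrays.

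Gene groups were 29 lists of pathways and cell type markers. With 1 probe set per gene (the one with the highest mean log2 value), 490 of 697 list members were measured. Each list was tested in each of the 7 comparisons with camera at a preset correlation of 0.01, adjusted over the lists of the comparison, and again with the correlation estimated from the data and with fry. Genes of a list were also counted when adjusted over the list alone. Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, per comparison, up to 6 genes higher and 6 lower with the largest log2 change among probe sets with 1 symbol, past the threshold and with arrays that do not overlap. It also names up to 4 members of each list past the threshold by smallest adjusted p (or up to 2 as values), 12 reference genes, and the 10 genes with the largest F. Of the reference genes, 2 are not reported here. A gene's direction in its other probe sets was counted, whatever the size of the change. A probe set counted in this way may lie near 0 or not pass the test.

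The alternatives were quantile normalisation, median-centring, the upper 50% of probe sets by mean signal, a fit of the 8 arrays alone, a variance trend, array weights, a replicate block, 1 probe set per gene, the mean over a gene's probe sets, a fold change of at least 2, an ordinary F test, pseudocounts of 1 and 64, and leaving out each array. One more, without the 3 arrays that lie apart on principal component 3, was chosen after seeing the data. Each comparison was also repeated over other splits of its arrays. Array quality was compared with two-sided exact permutation tests. The procedure was tested on simulated data, where probe sets from the upper 50% by mean signal were raised or lowered. Of 100 changed 2-fold, 53 were recovered (median absolute log2 change 1.01), and of 100 changed 4-fold, 96, with 8 unchanged probe sets called. Recovery of changes in dim probe sets was not tested. A simulated shift of 1 list by -1 gave an adjusted p of 4.9e-46, or 2.7e-09 with an estimated correlation, and 0 of 28 other lists were called. The simulated probe sets varied independently, so this does not test how often lists of correlated genes are called falsely. Figures were drawn with matplotlib (version 3.10.9) in Python (version 3.11.15).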

Results

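The series measured messenger RNA in the corpus luteum of rhesus macaques during simulated early pregnancy. The corpus luteum is the gland that forms from the ovulated follicle and secretes progesterone, and chorionic gonadotropin, the hormone of the early placenta, acts on it through the LH receptor. Females received human chorionic gonadotropin (hCG) from luteal day 9, by 2 injections per day into muscle, at doses that went up in 9 steps from 15 to 2880 IU. Corpora lutea were removed on luteal days 10, 12, 15 and 18, when the injections had run for 1, 3, 6 or 9 days. Untreated corpora lutea of luteal day 10 gave the baseline. Each of the 5 groups held 4 arrays. The labels do not say whether the corpora lutea of a group came from separate animals, so the p values measure only the spread between these samples. The day 10 groups share a luteal day. In the later groups the days of hCG, the luteal day and the dose of the rising regimen went up together, so a comparison with the baseline covers all of them.

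Each of the 20 arrays gave a signal for 52865 probe sets, of which 52707 were tested. The number of arrays limits the precision. Median signals ran from 31.5 to 46.2 intensity units, and 28.8% to 36.6% of probe sets per array had a signal under 16. Correlations between arrays were 0.959 to 0.979 within groups and 0.95 to 0.985 between groups. The median signal, the share under 16 and the differences between the 3' and 5' control probe sets of actin and GAPDH were compared with the untreated group. None of the 16 exact permutation tests, two-sided, passed the threshold (smallest exact p = 0.0571, adjusted p = 0.286, with 0.029 the smallest that 4 against 4 arrays allow). A lone test at 0.029 could not pass once adjusted over 16, so these tests do not show equal quality. The median signal averaged 44 in the untreated arrays and 39.4, 38.5, 39.5 and 42 on hCG days 10, 12, 15 and 18. On principal component 3, which held 8.4% of the variance, untreated replicate 2, hCG day 12 replicate 1 and hCG day 15 replicate 2 lay between -54.8 and -50.2, and the other 17 arrays between -4.8 and 23.6. In these 3 arrays LUM, which encodes the matrix protein lumican, had signals of 558 to 1657, against 7.53 to 152 in the others, and the interferon-induced gene ISG15 signals of 877 to 1177, against 210 to 664. Each of the 3 had the highest interferon response list mean of its group. Without them, the downward shift of that list passed on hCG days 10 and 15 (adjusted p = 0.0077 and 0.033) and not on day 12 (0.062). These arrays were singled out after the values were seen.

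Signals differed among the 5 groups for 2381 of the 52707 probe sets (9028 at an unadjusted p under 0.05), which covered 1224 named genes. Against the untreated group, 503 probe sets changed on hCG day 10, 152 on day 12, 681 on day 15 and 2054 on day 18. From one collection day to the next, 273 changed between days 10 and 12, and limma called 0 between days 12 and 15 and 0 between days 15 and 18. The arrays of the groups compared did not overlap for 7.96%, 5.7%, 7.2% and 11.2% of probe sets against the untreated group and for 4.59%, 2.45% and 3.67% in the steps, where chance gives 2.86%. The array medians of hCG days 10, 12, 15 and 18 differed from the untreated ones by -0.12, -0.14, -0.11 and -0.05 log2 units, a shift that median-centring takes out, so it gives changes relative to the median probe set. No called gene or list changed direction under median-centring or quantile normalisation. The number of shifted gene lists does not exclude chance: at least 2 of the 35 groupings of the 8 arrays of a comparison, the real one included, shifted as many. Of 43 list calls, 1 passed with an estimated correlation, and 23 ended with fry, which tests a list without comparing it with other genes.

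**Figure D1:**
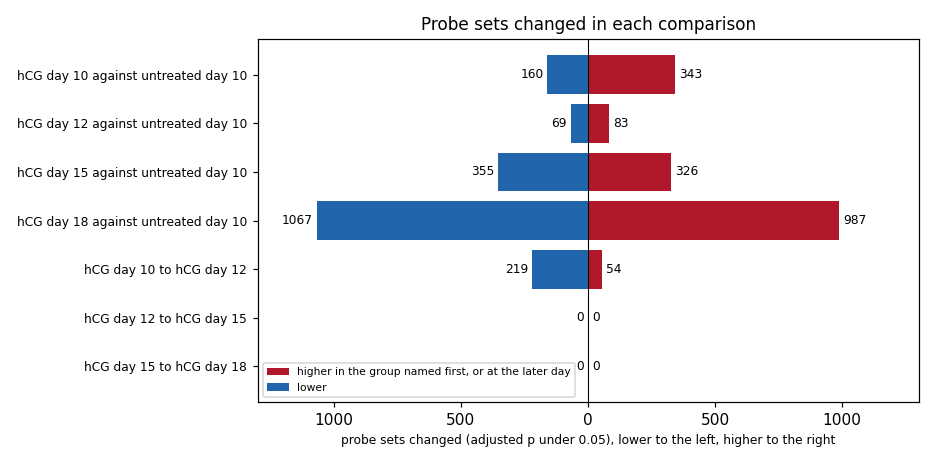
Probe sets that passed the test in each of the 7 comparisons (horizontal axis, number of probe sets; vertical axis, comparison), with those higher and those lower in the group named first, or at the later day, as separate bars. Against the untreated group 343 were higher and 160 lower on hCG day 10, and 987 higher and 1067 lower on day 18.

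The comparison of hCG day 10 with untreated day 10 asked what 1 day of hCG did at a matched luteal day. Genes of cholesterol synthesis, the growth factor gene IGF1 and an epithelial transcription factor gene were higher, and genes for a nerve growth factor receptor, a serotonin receptor and 2 serine/threonine kinases were among those lower. ELF5, a transcription factor of glandular epithelia (probe set MmugDNA.23160.1.S1_at), rose 7.49-fold (log2 change 2.90 ± 0.51, SE, n = 4 per group, adjusted p = 0.0076), from a signal of 51.4 ± 30.7 to 541 ± 319 (SD). HSD17B7, a hydroxysteroid dehydrogenase that also acts in cholesterol synthesis, rose 5.17-fold (2.37 ± 0.27, adjusted p = 0.00032), from 198 ± 87.7 to 1070 ± 328. NEDD1, a centrosome protein gene, fell 5.34-fold (-2.42 ± 0.22, adjusted p = 5.1e-05), from 773 ± 101 to 135 ± 40.3.

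Of the 503 probe sets changed on hCG day 10, 343 were higher and 160 lower, in 189 and 74 named genes, and 246 changed at least 2-fold. The share that was higher was 68.2%, and it was 86.1% after median-centring (463 higher and 75 lower). The other genes with the largest increases were TMPRSS7, a transmembrane serine protease (2.70 ± 0.41), ANKRD22 (2.55 ± 0.52, with 2 of its 3 probe sets higher), LOC695959 (2.50 ± 0.31) and MFSD2A, a lipid transporter (2.35 ± 0.28). Those with the largest decreases were S100A2 (-2.45 ± 0.45), the serotonin receptor gene HTR2B (-2.33 ± 0.34), the kinases STK26 (-2.04 ± 0.33) and STK17B (-1.83 ± 0.29), and NGFR (-1.68 ± 0.36, with its other probe set at -0.04). FST, which encodes the activin antagonist follistatin, rose by 2.23 ± 0.35 (adjusted p = 0.0028), IGF1 by 1.37 ± 0.22 (adjusted p = 0.0032) and ANGPTL4 by 1.30 ± 0.23 (adjusted p = 0.0079). BTC, an EGF receptor ligand (-1.24 ± 0.24), the vasodilator peptide gene ADM (-1.05 ± 0.24) and BMP4 (-1.01 ± 0.21) fell. After median-centring, ADM, BMP4 and SOX17 did not pass.

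In the list of cholesterol synthesis and uptake, 5 of 15 measured genes rose, 0 fell and 10 did not pass on hCG day 10. Counted when adjusted over the list alone, 12 rose. The list shifted up with camera (adjusted p = 5.6e-11, and adjusted p = 0.12 with an estimated correlation). DHCR7, a late enzyme of the pathway, rose by 1.77 ± 0.30, IDI1 by 1.16 ± 0.26, CYP51A1 by 1.07 ± 0.24 and FDFT1, squalene synthase, by 0.97 ± 0.20. Luteal steroidogenesis shifted up as well, with 2 of 23 genes higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.12 with an estimated correlation). Its members that rose were HSD17B7 and MRAP, a partner of melanocortin receptors (0.78 ± 0.15, with its other probe set at 0). Antioxidant defence shifted up with 1 of 18 genes higher, GCLC (0.88 ± 0.19), and 5 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.21 with an estimated correlation). Heat shock and tissue handling did so with 1 of 9 genes higher, DNAJB1 (0.74 ± 0.13), and 1 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.15 with an estimated correlation). That call ended without hCG day 10 replicate 1 (adjusted p = 0.059).

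The interferon response list shifted down on hCG day 10 although 0 of 18 genes passed alone, over all genes or adjusted over the list alone (adjusted p = 0.00018, and adjusted p = 0.36 with an estimated correlation). None of its 18 genes was above 0, and the median was -0.50, with IFIT1 at -1.02 ± 0.39 (adjusted p = 0.27). In this list untreated replicate 2 stood 0.46 above the mean of the untreated arrays. Endothelial cells shifted down with 1 of 20 genes lower, SOX17 (-0.67 ± 0.16), and 2 adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation). So did MHC class II and antigen presentation (0 of 14, 1 lower adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation). Both calls ended without untreated replicate 2 (adjusted p = 0.054 and 0.41) and without hCG day 10 replicate 1 (0.059 and 0.059). Cell cycle (0 of 19, 0 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.48 with an estimated correlation) lost its call without hCG day 10 replicate 2 (0.26). Apoptosis (0 of 21, 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.36 with an estimated correlation) lost it without untreated replicates 1 and 2 (0.15 and 0.053) and without hCG day 10 replicates 2 and 3 (0.076 and 0.11).

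The count of 503 was 279, 298 and 265 without untreated replicates 2, 3 and 4, 228 and 275 without hCG day 10 replicates 3 and 4, 172 in a fit of the 8 arrays alone and 324 without the 3 arrays apart on component 3. Of 27 calls of named genes, 11 ended without 1 array, with highest adjusted p of 0.057 to 0.15: ANKRD22, NGFR, MRAP, FDFT1, CYP51A1, IDI1, BTC, ADM, SOX17, GCLC and BMP4. Each of the 8 arrays ended 3 to 9 of them, and the fit of the 8 arrays alone ended 16, ELF5, TMPRSS7, S100A2, STK26, FST and DNAJB1 among them.

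The comparison of hCG day 12 with untreated day 10 covered 3 days of hCG. Cholesterol synthesis genes were higher on day 12 as well, together with genes for a chromatin protein and for the transcription factor CEBPA, and S100A2, NEDD1 and the 2 kinase genes were lower. HMGB3, a high mobility group protein gene (probe set MmuSTS.3830.1.S1_at), rose 7.98-fold (log2 change 3.00 ± 0.38, SE, n = 4 per group, adjusted p = 0.0014), from a signal of 333 ± 105 to 2782 ± 926. Of its 4 probe sets 3 were higher, but only this 1 passed the test, and the lowest was at -0.27. CEBPA rose 3.64-fold (1.86 ± 0.26, adjusted p = 0.0029), from 447 ± 53.0 to 1683 ± 318. F2RL1, a protease-activated receptor gene, fell 3.82-fold (-1.93 ± 0.24, adjusted p = 0.0011), from 1421 ± 359 to 377 ± 186.

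Of the 152 probe sets changed on hCG day 12, 83 were higher and 69 lower, in 44 and 34 named genes, and 107 changed at least 2-fold. The share that was higher was 54.6%, and 73.9% after median-centring (133 higher and 47 lower). PLCG2, a phospholipase of immune receptor signalling, rose by 2.39 ± 0.49 (its other probe set was at 0.02), LOC708750 by 1.68 ± 0.26, the antiproliferative gene TOB1 by 1.68 ± 0.24 and EBP, an enzyme of cholesterol synthesis, by 1.68 ± 0.28. The other largest decreases were in S100A2 (-2.38 ± 0.45), NEDD1 (-2.36 ± 0.29), MRO (-2.13 ± 0.41, with 1 of its 3 probe sets lower), STK17B (-2.10 ± 0.31) and STK26 (-1.90 ± 0.33). MRAP rose by 1.17 ± 0.15 (adjusted p = 0.0014, 1 of its 2 probe sets), and BTC (-1.46 ± 0.24) and ID4, an inhibitor of helix-loop-helix factors (-1.08 ± 0.19), were lower.

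In the cholesterol synthesis and uptake list, 5 of 15 genes rose on hCG day 12 and 0 fell, or 11 and 0 adjusted over the list alone (adjusted p = 1.6e-15, and adjusted p = 0.071 with an estimated correlation). Besides EBP, they included DHCR7 (1.52 ± 0.30), IDI1 (1.36 ± 0.26) and FDFT1 (1.13 ± 0.20). Antioxidant defence shifted up with 1 of 18 genes higher, MGST1, a glutathione transferase (1.12 ± 0.18), and 1 adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.16 with an estimated correlation). Smooth muscle and pericytes shifted up with 0 of 11 genes past the test and 2 higher adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation). MYH11, smooth muscle myosin, was at 0.84 ± 0.27 (adjusted p = 0.26). The cAMP and immediate early response list shifted down with 1 of 23 genes lower, BTC, and 3 adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.45 with an estimated correlation), a call that ended without untreated replicate 1 (0.11). Interferon response (0 of 18, 0 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.6 with an estimated correlation) shifted down too, but not without untreated replicate 2 (0.25) or hCG day 12 replicate 4 (0.14). Cell cycle (0 of 19, 1 lower adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.6 with an estimated correlation) lost its call without untreated replicates 1, 2 and 3 (0.094, 0.063 and 0.085) and without hCG day 12 replicates 1 and 4 (0.079 and 0.068).

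The count of 152 was 77 and 82 without untreated replicates 1 and 4, 290, 73 and 82 without hCG day 12 replicates 2, 3 and 4, 7 in a fit of the 8 arrays alone, 254 with array weights and 93 without the 3 arrays apart on component 3. Without untreated replicate 4, 10 lists shifted instead of 6. Of 19 calls of named genes, 8 ended without 1 array, with highest adjusted p of 0.06 to 0.13, namely PLCG2, S100A2, MRO, STK26, FDFT1, IDI1, DHCR7 and ID4. Untreated replicates 1, 2 and 4 and all 4 hCG day 12 arrays ended 1 to 7 each, and the fit of the 8 arrays alone kept only HMGB3 and CEBPA.

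The comparison of hCG day 15 with untreated day 10 covered 6 days of hCG. HP, CYBRD1, CYP17A1 and genes of cholesterol synthesis were higher, and the EGF receptor ligand gene AREG, the progesterone-synthesis gene HSD3B2 and cell cycle genes were lower. HP, which encodes the haemoglobin-binding protein haptoglobin (probe set MmuSTS.598.1.S1_at), rose 8.11-fold (log2 change 3.02 ± 0.72, SE, n = 4 per group, adjusted p = 0.042), from a mean signal of 69.2 to 843. This call ended in 13 of 20 fits without 1 array, in the fit of the 8 arrays alone, and with a pseudocount of 1 or 64. CYBRD1, a ferric reductase gene, rose 5.21-fold (2.38 ± 0.30, adjusted p = 0.00053), from 190 to 1034. AREG, amphiregulin, fell 8.21-fold (-3.04 ± 0.45, adjusted p = 0.0018), from 8115 to 1166. CYP17A1, the enzyme of androgen synthesis, rose 3.74-fold (1.90 ± 0.34, adjusted p = 0.0062, with its other probe set at 0.29). HSD3B2, which makes progesterone from pregnenolone, fell 1.96-fold (-0.97 ± 0.21, adjusted p = 0.024).

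Of the 681 probe sets changed on hCG day 15, 326 were higher and 355 lower, in 163 and 188 named genes, and 342 changed at least 2-fold. The share that was higher was 47.9%, and 64.7% after median-centring (408 higher and 223 lower). HMGB3 (2.84 ± 0.38, with 1 of its 4 probe sets higher), the ion channel gene TRPM3 (2.53 ± 0.30), DPYSL3 (2.47 ± 0.38) and BICDL1 (2.15 ± 0.28) were the other largest increases. S100A2 (-3.19 ± 0.45), SLC17A4 (-2.79 ± 0.62), NEDD1 (-2.48 ± 0.29), the prostaglandin receptor gene PTGDR (-2.47 ± 0.35) and MRO (-2.33 ± 0.41, with 1 of its 3 probe sets lower) were the other largest decreases. MRAP (0.99 ± 0.15, 1 of its 2 probe sets) and POR (0.89 ± 0.19, 1 of its 4 probe sets) rose. So did IGFBP1 (1.39 ± 0.26), ANGPTL4 (1.05 ± 0.23) and BCL2L11 (0.75 ± 0.16, 3 of its 6 probe sets). FSTL3 (-1.80 ± 0.29), MMP10 (from a mean signal of 41.7 to 6.47), MMP1 (32.7 to 4.34), BTC (-1.15 ± 0.24), ID4 (-1.09 ± 0.19), PGR, the progesterone receptor gene (-0.95 ± 0.19), HK1 (-0.92 ± 0.21, 3 of its 4 probe sets) and KCNJ8 (-0.75 ± 0.14) fell. The day 15 signals of MMP10 and MMP1 lay under the 16 added before the logarithm, so the sizes of their changes are not resolved: -1.30 and -1.15 with 16 added, -2.88 and -2.68 with 1, and -0.56 and -0.47 with 64. MMP10 did not pass with 1 added, and MMP1 did not pass with 64. After median-centring, HK1 and KCNJ8 did not pass.

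In the cholesterol synthesis and uptake list 8 of 15 genes rose on hCG day 15 and 0 fell, or 10 and 0 adjusted over the list alone (adjusted p = 9.3e-14, and adjusted p = 0.063 with an estimated correlation). EBP rose by 1.81 ± 0.28, IDI1 by 1.69 ± 0.26, CYP51A1 by 1.41 ± 0.24 and FDFT1 by 1.27 ± 0.20. In the cell cycle list 5 of 19 genes fell and 0 rose, or 15 and 0 adjusted over the list alone, and none was above 0 (adjusted p = 5.7e-14, and adjusted p = 0.063 with an estimated correlation). CCNB1 and CCNB2, the B-type cyclins, were at -1.22 ± 0.20 and -1.09 ± 0.23, the proliferation marker MKI67 at -1.10 ± 0.23 and CCNA2 at -0.86 ± 0.16. Antioxidant defence shifted up with MGST1 (1.33 ± 0.18) as 1 of 18 genes higher and 2 adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.15 with an estimated correlation).

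Also on hCG day 15, 4 other lists shifted down. The cAMP and immediate early response list had 2 of 23 genes lower, AREG and BTC, and 5 adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.52 with an estimated correlation). Its call ended without untreated replicates 1 and 4 (0.24 and 0.051) and without hCG day 15 replicates 3 and 4 (0.32 and 0.08). Extracellular matrix and fibroblasts had 0 of 19 genes past the test and 2 lower adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation), and lost its call without untreated replicate 1 (0.062). THY1, a fibroblast surface marker, was at -0.70 ± 0.17 (adjusted p = 0.053). Endothelial cells (0 of 20, 0 adjusted over the list alone, adjusted p = 0.043, and adjusted p = 0.52 with an estimated correlation) lost the call without untreated replicates 1, 2 and 3 (0.061, 0.088 and 0.066) and hCG day 15 replicates 1 and 2 (0.21 and 0.19). Interferon response (0 of 18, 0 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation) lost it without untreated replicate 2 (0.14) and hCG day 15 replicate 4 (0.081).

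The count of 681 was 379 and 428 without untreated replicates 1 and 4, 321 without hCG day 15 replicate 4, 230 in a fit of the 8 arrays alone and 359 without the 3 arrays apart on component 3. Without untreated replicate 1, 4 lists shifted instead of 7. Of 36 calls of named genes, 13 ended without 1 array, with highest adjusted p of 0.062 to 0.15, namely HP, SLC17A4, POR, HSD3B2, BTC, PGR, ANGPTL4, MMP1, MMP10, MKI67, CCNB2, BCL2L11 and HK1. Each of the 8 arrays ended 2 to 11 of them, and the fit of the 8 arrays alone ended 16, CCNB1, FDFT1, ID4, KCNJ8 and MRAP among them.

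The comparison of hCG day 18 with untreated day 10 covered 9 days of hCG and had the most probe sets past the test. HP rose 72.0-fold (log2 change 6.17 ± 0.72, SE, n = 4 per group, adjusted p = 4.7e-05), from a mean signal of 69.2 to 5862. HSD3B2 fell 3.56-fold (-1.83 ± 0.21, adjusted p = 4.4e-05), from 8320 to 2340, while STAR, which carries cholesterol into mitochondria, was at 0.23 ± 0.17 (adjusted p = 0.62). The group means of STAR, 14873 to 17387, lay near the highest signals of the arrays (14955 in the array with the lowest maximum), where an increase may not register. CYP17A1 rose 4.60-fold (2.20 ± 0.34, adjusted p = 0.00067), with its other probe set at 0.36. AREG fell 14.0-fold (-3.80 ± 0.45, adjusted p = 6.1e-05), from 8115 to 626. CCNB1 fell 3.63-fold (-1.86 ± 0.20, adjusted p = 3.1e-05), from 444 to 110.

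**Figure D2:**
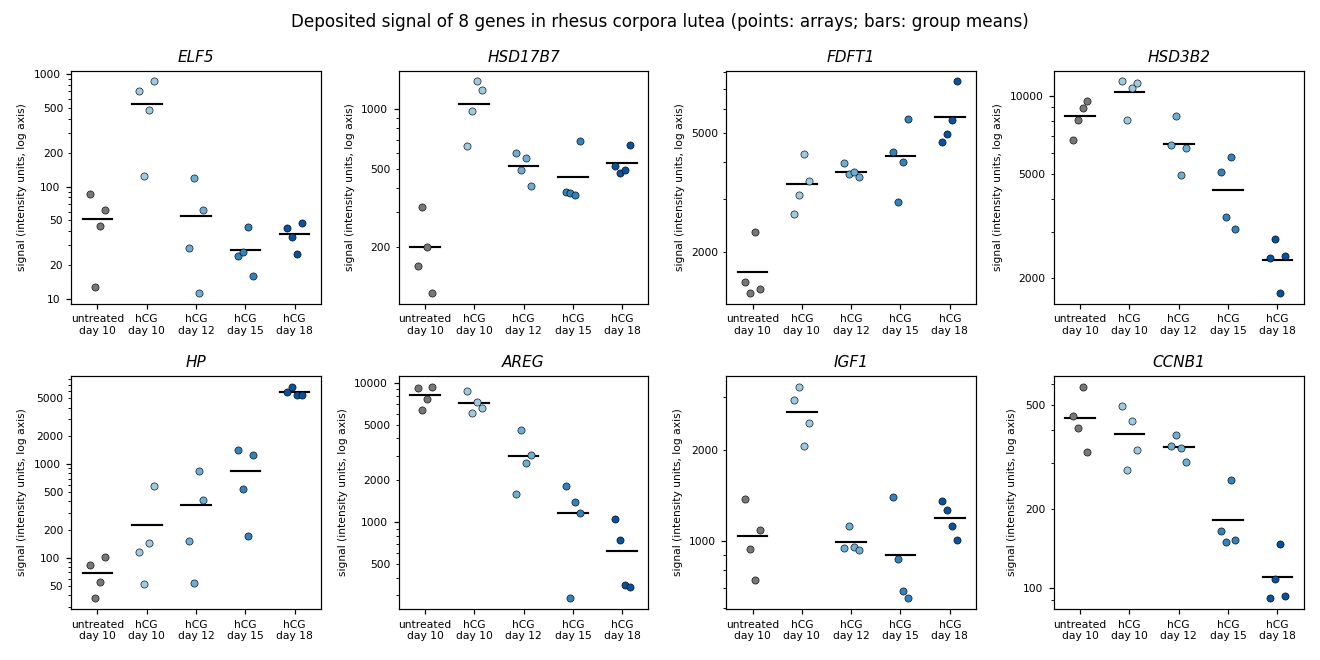
Deposited signal of 8 genes (vertical axis, intensity units, log axis) in the 5 groups (horizontal axis), with 1 point per array and a bar at each group's mean. ELF5 lay between 125 and 859 on hCG day 10 and between 12.8 and 85.6 untreated, HP between 5409 and 6695 on day 18 and between 36.8 and 102 untreated, and HSD3B2 between 1742 and 2824 on day 18 and between 6740 and 9501 untreated.

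Of the 2054 probe sets changed on hCG day 18, 987 were higher and 1067 lower, in 493 and 583 named genes, and 845 changed at least 2-fold. TRPM3 (3.46 ± 0.30), DPYSL3 (3.25 ± 0.38), MS4A8 (3.02 ± 0.34, with 2 of its 3 probe sets higher) and CYBRD1 (3.00 ± 0.30) were among the largest increases. TENM2 rose from a mean signal of 7.23, under the 16 added before the logarithm, to 426. Its size, and so its rank, is not resolved: 3.99 with 16 added, 5.8 with 1 and 2.55 with 64. S100A2 (-3.98 ± 0.45), the phosphatase gene DUSP5 (-3.24 ± 0.81), CYP3A4 (-3.13 ± 0.49, 3 of its 4 probe sets), PAPSS2, which supplies the donor for sulphation (-2.90 ± 0.28), and MRO (-2.87 ± 0.41, 1 of its 3 probe sets) were the other largest decreases. For PAPSS2, 1 of 4 probe sets passed the test, and the one that changed least was at -0.02. In luteal steroidogenesis 4 of 23 genes rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.65). POR, which passes electrons to these enzymes, rose by 1.18 ± 0.19 in 1 of its 4 probe sets, and HSD11B1, which activates cortisone, was at -1.13 ± 0.13.

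In the cholesterol synthesis and uptake list 10 of 15 genes rose on hCG day 18 and 0 fell, with the same counts adjusted over the list alone (adjusted p = 1.9e-12, and adjusted p = 0.085 with an estimated correlation). MVD rose by 2.36 ± 0.35, EBP by 2.31 ± 0.28, FDFT1 by 1.71 ± 0.20 and CYP51A1 by 1.61 ± 0.24. In cholesterol efflux and LXR targets 2 of 12 genes rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.085 with an estimated correlation). These were NPC2, a lysosomal cholesterol carrier (0.74 ± 0.16), and PLTP (0.58 ± 0.15). Antioxidant defence shifted up with 2 of 18 genes higher, MGST1 (1.49 ± 0.18) and SOD1 (0.89 ± 0.16), and 3 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation). That call ended under quantile normalisation.

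In the cell cycle list 13 of 19 genes fell on hCG day 18 and 0 rose, or 17 and 0 adjusted over the list alone (adjusted p = 7.9e-18, and adjusted p = 0.051 with an estimated correlation). The median change was -1 and none was above 0. CCNB2 was at -1.77 ± 0.23, the centromere protein CENPF at -1.68 ± 0.19 and CCNA2 at -1.33 ± 0.16. The list mean per array lay 0.92 to 1.24 log2 units lower than the untreated mean, at -1.07, -1.24, -0.92 and -1.15, against -0.22 to 0.14 in the untreated arrays.

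The macrophages and monocytes list shifted up on hCG day 18, with 3 of 15 genes higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.36 with an estimated correlation). CSF1R, the receptor for a macrophage growth factor, rose by 1.06 ± 0.23 (adjusted p = 0.012), VSIG4 by 1.15 ± 0.30 and the complement gene C1QC by 1.08 ± 0.28. The arrays overlapped: the day 18 list means were 1.27, 0.32, 0.97 and 0.38 from the untreated mean, and the untreated ones 0.58, 0.38, -0.27 and -0.68. Other leukocyte genes that rose were CD96 (1.57 ± 0.33, or 2.28 with 1 and 0.85 with 64 instead of 16 added to an untreated signal of 14.8, in 1 of its 3 probe sets), GZMA, a cytotoxic lymphocyte protease (0.91 ± 0.19), and JCHAIN (1.17 ± 0.30, 1 of its 2 probe sets). The lists of T and NK lymphocytes (2 of 12 higher, adjusted p = 0.098), B lymphocytes and plasma cells (1 of 9, adjusted p = 0.078) and neutrophils (0 of 9, adjusted p = 0.35) did not shift. HBB, haemoglobin beta, was at 1.06 ± 0.41 (adjusted p = 0.18).

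Extracellular matrix and fibroblasts shifted down on hCG day 18, with 4 of 19 genes lower and 0 higher and the same counts adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.38 with an estimated correlation). THY1 was at -1.06 ± 0.17, COL5A2 at -0.85 ± 0.17, fibronectin gene FN1 at -0.91 ± 0.22 and VCAN at -1.46 ± 0.37. The call ended without hCG day 18 replicate 3 (0.083). The cAMP and immediate early response list shifted down with 5 of 23 genes lower and 0 higher, or 6 and 0 adjusted over the list alone (adjusted p = 0.009, and adjusted p = 0.4 with an estimated correlation), a call that ended without untreated replicate 1 (0.086). After AREG, TNFAIP6 was at -1.37 ± 0.25, BTC at -0.95 ± 0.24 and IER2 at -0.64 ± 0.14.

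The count of 2054 stayed within 1.5 times in each fit without 1 array. Of 65 calls of named genes, 19 ended without 1 array, with highest adjusted p of 0.054 to 0.15: DUSP5, PLTP, BTC, PENK, PGRMC2, RECK, MMP16, MMP1, FN1, VCAN, ACTG2, C1QC, VSIG4, JCHAIN, TAP1, PMAIP1, HK2, PFKFB3 and SLC2A1. Each of the 8 arrays ended 8 to 17 of them, and the fit of the 8 arrays alone ended 14, CSF1R, GZMA, IER2 and IGFBP4 among them.

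**Figure D3:**
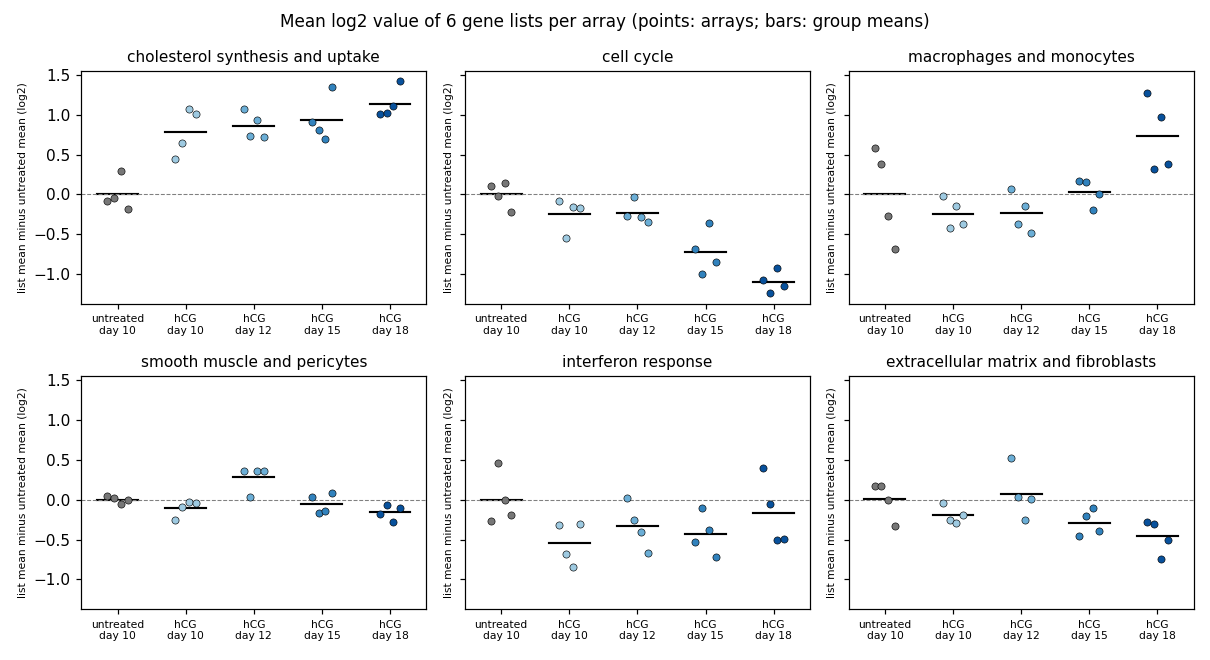
Mean log2 signal of 6 gene lists minus the untreated mean (vertical axis, log2 units) in the 5 groups (horizontal axis), with 1 point per array and a bar at each group's mean. Cholesterol synthesis and uptake lay at 1.01, 1.02, 1.11 and 1.42 in the 4 arrays of hCG day 18, cell cycle at -1.07, -1.24, -0.92 and -1.15, and macrophages and monocytes at 1.27, 0.32, 0.97 and 0.38, a range that overlaps the untreated arrays.

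The step from hCG day 10 to day 12 asked what changed between 1 and 3 days of hCG. It was mostly downward, and 5 of the 6 genes with the largest rise after 1 day of hCG were among the 6 with the largest fall here. Both comparisons use the hCG day 10 arrays, so this overlap is no separate measurement. ANKRD22 fell 10.2-fold (log2 change -3.35 ± 0.52, SE, n = 4 per group, adjusted p = 0.0032), from a mean signal of 409 to 28.7 (SD 28.7). Of its 3 probe sets 2 were lower, and the highest was at 0.15. With a pseudocount of 1, 7 named calls of this step ended, ANKRD22 and TMPRSS7 among them. TMPRSS7 was at -3.07 ± 0.45, ELF5 at -2.94 ± 0.51, LOC695959 at -2.80 ± 0.31, MFSD2A at -2.45 ± 0.28 and TDRD9 at -2.35 ± 0.23. IGF1 fell 2.65-fold (-1.41 ± 0.22, adjusted p = 0.0031), from 2682 to 989. Of the 273 probe sets changed, 54 were higher and 219 lower, in 25 and 113 named genes. The largest increases were in the matrix gene MXRA5 (1.56 ± 0.27), LOC717047 (1.54 ± 0.34), KIAA1217 (1.38 ± 0.23), CYBRD1 (1.25 ± 0.19), PTPN22 (1.20 ± 0.23) and ENPP2, which makes lysophosphatidic acid (1.19 ± 0.26).

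Smooth muscle and pericytes shifted up between hCG days 10 and 12, with 0 of 11 genes past the test and 3 higher adjusted over the list alone (adjusted p = 0.00015, and adjusted p = 0.042 with an estimated correlation, the 1 list call of 43 that passed with it). SYNM was at 0.81 ± 0.22 (adjusted p = 0.15). Cholesterol efflux and LXR targets shifted up with 0 of 12 genes past the test, also adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.19 with an estimated correlation). That call ended without hCG day 10 replicates 1, 2 and 4 (0.057, 0.052 and 0.059) and without hCG day 12 replicate 1 (0.19). In matrix proteases and inhibitors, which did not shift, 2 of 25 genes rose and 0 fell, with the same counts adjusted over the list alone. These were the aggrecanase gene ADAMTS5 (0.95 ± 0.19) and ADAMTS2 (0.89 ± 0.19).

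The count of 273 was 170, 169 and 168 without hCG day 10 replicates 1, 3 and 4, 179, 174 and 151 without hCG day 12 replicates 1, 3 and 4 and 56 in a fit of the 8 arrays alone. The 2 lists shifted became 1 without hCG day 10 replicate 2 or 4 or hCG day 12 replicate 1 and 4 without hCG day 12 replicate 3 or 4 or hCG day 15 replicate 2. Of 15 calls of named genes, 5 ended without 1 array, with highest adjusted p of 0.075 to 0.16, namely LOC717047, PTPN22, ENPP2, ADAMTS5 and ADAMTS2. Each of the 8 arrays ended 3 to 5 of them, and the fit of the 8 arrays alone ended 9, ANKRD22, ELF5, TMPRSS7 and CYBRD1 among them.

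The step from hCG day 12 to day 15 had 0 probe sets past the test with limma (2705 at an unadjusted p under 0.05, smallest adjusted p = 0.14). In this step 5 lists shifted. Cell cycle shifted down with 0 of 19 genes past the test and 11 lower adjusted over the list alone (adjusted p = 4e-13, and adjusted p = 0.077 with an estimated correlation). CCNB1 was at -0.90 ± 0.20 (adjusted p = 0.43). Extracellular matrix and fibroblasts shifted down with 0 of 19 and 6 lower adjusted over the list alone (adjusted p = 4e-06, and adjusted p = 0.21 with an estimated correlation). COL1A1 was at -1.40 ± 0.30 (adjusted p = 0.34) and COL6A3 at -0.80 ± 0.17 (adjusted p = 0.32). Smooth muscle and pericytes did so with 0 of 11 and 3 lower adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.061 with an estimated correlation). Endothelial cells shifted down (0 of 20, 0 adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.54 with an estimated correlation), but not without hCG day 12 replicates 1, 2 and 4 (0.17, 0.12 and 0.055) or hCG day 15 replicates 1 and 2 (0.29 and 0.33). Macrophages and monocytes shifted up (0 of 15, 0 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.85 with an estimated correlation), but not without hCG day 12 replicates 2 and 4 (0.081 and 0.13) or hCG day 15 replicates 1 and 2 (0.12 and 0.057). The probe set count was 4 without hCG day 12 replicate 1, 2 without hCG day 15 replicate 3 and 2 with a pseudocount of 1. The lists shifted were 3 without hCG day 12 replicate 4 and 3 without hCG day 15 replicate 2.

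The step from hCG day 15 to day 18 also had 0 probe sets past the test with limma (3688 at an unadjusted p under 0.05, smallest adjusted p = 0.27, and 1 probe set without hCG day 18 replicate 1). In this step 7 lists shifted. Macrophages and monocytes shifted up with 0 of 15 genes past the test and 9 higher adjusted over the list alone (adjusted p = 3.9e-10, and adjusted p = 0.21 with an estimated correlation). CSF1R was at 1.09 ± 0.23 (adjusted p = 0.32). MHC class II and antigen presentation shifted up with 0 of 14 and 2 higher adjusted over the list alone (adjusted p = 0.00083, and adjusted p = 0.21 with an estimated correlation). CD74, the invariant chain, was at 1.22 ± 0.33 (adjusted p = 0.42). Cell cycle shifted down with 0 of 19 and 7 lower adjusted over the list alone (adjusted p = 2.3e-06, and adjusted p = 0.21 with an estimated correlation). CENPF was at -0.96 ± 0.19 (adjusted p = 0.27). Oxidative phosphorylation shifted down with 0 of 23, also adjusted over the list alone (adjusted p = 3e-04, and adjusted p = 0.35 with an estimated correlation). Upward shifts of T and NK lymphocytes (0 of 12, adjusted p = 0.028), B lymphocytes and plasma cells (0 of 9, adjusted p = 0.028) and chemokines and inflammatory cytokines (0 of 24, adjusted p = 0.017) had 0 genes past the test adjusted over the list alone as well, and each had an adjusted p = 0.21 with an estimated correlation. The T and NK call ended without hCG day 15 replicates 1, 2 and 4 and hCG day 18 replicate 3 (0.053, 0.086, 0.094 and 0.099). The B cell call ended without hCG day 15 replicates 1 and 2 and hCG day 18 replicates 3 and 4 (0.076, 0.091, 0.1 and 0.095), and the chemokine call without hCG day 15 replicate 2 and hCG day 18 replicate 1 (0.069 and 0.13).

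Among the reference genes, 6 had a named probe set. STAR was at 0.06, 0.08, 0.07 and 0.23 on hCG days 10, 12, 15 and 18 and passed in none of these comparisons. CYP19A1, aromatase, was at 0.68, 0.65, 0.61 and 0.78 (SE 0.26), INHA at 0.28, 0.37, 0.35 and 0.47 (SE 0.17) and the relaxin gene RLN2 at -0.24, 0.76, 0.85 and 1.04 (SE 0.42), and none of them passed (smallest adjusted p = 0.11). The highest group mean of RLN2, 15600, lay above the lowest array maximum of 14955, so an increase may not register in full there either. Without untreated replicate 1, RLN2 was at -0.76, 0.24, 0.33 and 0.52, and without untreated replicate 4, CYP19A1 was at 0.47, 0.44, 0.4 and 0.57. HSD3B2 was at 0.31 and -0.37 on days 10 and 12, where it did not pass (adjusted p = 0.59 and 0.56), and passed on days 15 and 18. PGR was at -0.52 and -0.80 on days 10 and 12 (adjusted p = 0.25 and 0.09), and fell on days 15 (-0.95) and 18 (-0.87). The genes CYP11A1, LHCGR, VEGFA and PTGS2 had no probe set with their symbol alone.

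Comparisons with a shared untreated group overlap in part through those arrays. Of the 681 probe sets changed on day 15, 579 also changed on day 18, all in the same direction, where independent calls would give 6.1 higher and 7.2 lower in both. With the untreated arrays split between the comparisons, 120 to 169 were shared in the same direction over 6 splits. With fewer untreated arrays, day 15 itself then had only 165 to 351 calls. The lower shared counts therefore do not show how much of the overlap came from the shared arrays. In 20 simulations without an effect no comparison had more than 1 call, so a shared count of at most 0 there says nothing of how far the shared arrays raise the 579. At an unadjusted p under 0.05, 3587 were shared in the same direction, against 526 to 615 in these simulations. The simulations held no effect and varied probe sets independently. This contrast therefore does not show how much of the overlap came from the shared arrays either. Days 12 and 15 shared 126 of 152, all in the same direction, against 0.5 and 0.5 (18 to 39 with split untreated arrays, where day 12 had 32 to 145 calls). Days 10 and 18 shared 157, of which 70 were higher in both, 60 lower in both and 27 opposite, against 6.4 and 3.2. With split untreated arrays, 15 to 35 were in the same direction and up to 13 opposite, where day 10 had 98 to 229 calls instead of 503.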

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

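Tests chosen only after the result was seen are those of the shares of endothelial cells and of fibroblasts behind the cell cycle genes and of blood behind the macrophage markers.

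In groups of 4 arrays, 495 sets of values of named genes and lists were searched for 1 array far from the others, by the ratio of its gap to the whole range. This ratio passed Dixon's limit in 22 sets, where chance gives about 1 in 20 groups (24.8 expected). No array had more than 3 of them. RLN2 was low in untreated replicate 1 (ratio 0.908, log2 signal 11.32) and in hCG day 10 replicate 1 (0.872, 11.28). CYP19A1 was low in untreated replicate 4 (0.953, 11.9). In the untreated group the other ratios were 0.84 for the angiogenic factors list and 0.9 for PENK in replicate 1, 0.864 for STK26 in replicate 2 and 0.847 for PMAIP1 in replicate 3. On hCG day 10 they were 0.837 for HSD3B2 in replicate 2 and 0.848 for BMP4 in replicate 3. On hCG day 12 they were 0.989 for smooth muscle and pericytes, 0.831 for F2RL1 and 0.862 for IGF1 in replicate 2, and 0.892 for neutrophils and 0.876 for CSPG4 in replicate 3. On hCG day 15 they were 0.939 for MRO and 0.878 for TRPM3 in replicate 2, and 0.845 for T and NK lymphocytes and 0.83 for CCNB1 in replicate 3. On hCG day 18 they were 0.865 for MHC class II and antigen presentation and 0.843 for BCL2L11 in replicate 1, and 0.837 for BTC and 0.869 for CCNB2 in replicate 3.

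Signals under hCG differed between collection days by the test of the step itself, where days of hCG, luteal day and dose went up together. Between days 10 and 12, 273 probe sets and 2 lists differed, between days 12 and 15 0 probe sets and 5 lists, and between days 15 and 18 0 probe sets and 7 lists. With an estimated correlation, 1, 0 and 0 lists differed in these steps, and 16, 9 and 5 of the 35 splits of the arrays, the real one included, gave as many lists, so chance cannot be excluded for the lists. The named genes of the first of these steps were at 1.56 (MXRA5), 1.54 (LOC717047), 1.38 (KIAA1217), 1.25 (CYBRD1), 1.20 (PTPN22), 1.19 (ENPP2), 0.95 (ADAMTS5), 0.89 (ADAMTS2), -3.35 (ANKRD22), -3.07 (TMPRSS7), -2.94 (ELF5), -2.80 (LOC695959), -2.45 (MFSD2A), -2.35 (TDRD9) and -1.41 (IGF1). Among the 158 array control probe sets, outside the main measurement, 1 changed from hCG day 15 to day 18 and 0 in each of the other 6 comparisons.

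All 35 splits of the 8 arrays of a comparison were tested. For the probe set counts, only the real split (1 of 35, the smallest share possible) gave as many against the untreated group. These were 503 on day 10 (highest other split 1), 152 on day 12 (9), 681 on day 15 (1) and 2054 on day 18 (1), and likewise 273 between days 10 and 12 (2). With 35 splits and several comparisons, this makes chance less likely but cannot exclude it. The other splits mix both groups, so a real difference widens their spread and lowers their counts. For days 12 to 15 and 15 to 18, where the real count is 0, all 35 splits gave as many. The highest other split of the former called 30. It set hCG day 12 replicates 1 and 2 and hCG day 15 replicates 1 and 3 against the rest. This may reflect a structure of the samples, but what these arrays share was not tested. The highest of the latter called 2. For the number of lists shifted, chance cannot be excluded. As many were shifted in 2 of 35 splits for day 10 (9 lists, highest other 11), 5 for day 12 (6, highest 8), 7 for day 15 (7, highest 11), 7 for day 18 (7, highest 12), 16 between days 10 and 12 (2, highest 4), 9 between days 12 and 15 (5, highest 6) and 5 between days 15 and 18 (7, highest 7). For the test among the 5 groups, 1 of 100 splits, the real one, gave 2381 probe sets (highest other 11).

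In the cell cycle list 13 of 19 genes were lower on hCG day 18, and all 4 arrays lay below the 4 untreated ones. With an estimated correlation the list did not pass (adjusted p = 0.051). Scaling of the arrays as the cause is excluded, since the median change was still -0.95 under the scaling that brought it closest to 0. An even fall in the share of endothelial cells would not alone account for the change, since the list mean fell 0.90 further than theirs (difference -0.90). A loss of only the dividing endothelial cells is not excluded, since a list of general endothelial markers may not show it. A smaller share of fibroblasts and matrix could not be decided: the difference was -0.63, but the arrays of the 2 groups overlapped. Less cell division after 9 days of hCG, at a higher dose or at a later luteal day may account for it, as a hypothesis, and the design does not part these.

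Probe sets higher after 1 day of hCG were lower again after 3 days, with medians of 1.04, 0.27, 0.11 and 0.08 on days 10, 12, 15 and 18 for the 343 called higher. For the 160 called lower, the medians were -0.92, -0.54, -0.51 and -0.52. An effect of hCG day 12 replicate 3 is excluded, since the median step was -0.69 without it (-0.68 with it). Chance highs of the hCG day 10 arrays remain open in part. With 2 of these arrays used for the call and 2 for the step, the 6 choices gave median steps of -1.3, -0.88, -0.85, -0.67, -0.81 and -0.43, and the last of these does not exclude that a share of the step may come from this source.

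The macrophages and monocytes list shifted up on hCG day 18, with 3 of 15 genes higher, and did not pass with an estimated correlation (adjusted p = 0.36). The arrays overlapped the untreated ones. Dependence of the list median on 1 hCG day 18 array is excluded, since it was 0.63 at the lowest without 1 array. The calls of C1QC and VSIG4 did end without hCG day 18 replicate 1 or 3, and without untreated replicate 3 or 4. That of C1QC also ended without hCG day 18 replicate 2, and that of VSIG4 without untreated replicate 2. In the fit of the 8 arrays alone, CSF1R, C1QC and VSIG4 did not pass. Day 18 replicates 1 and 3 had the highest list means (1.27 and 0.97), and dependence on both together was not tested. Scaling is excluded, since the list median was 0.79 at the lowest under the other scalings. Blood left in the tissue could not be decided: HBB was at 1.06 (95% confidence interval 0.21 to 1.92, adjusted p = 0.18), near the median of 0.79 of the macrophage list. The erythrocyte list had a median of 0.16 with 0 of 5 genes past the test (adjusted p = 0.48). ALAS2 was at 0.16, with a 95% confidence interval of -0.72 to 1.04 that holds 0.79. EPB42, at 0.19, had a signal of 20.4 untreated, and AHSP and HEMGN, at -0.01 and -0.11, lay under 16. More macrophages in the tissue, or more of these transcripts per cell, may account for it, as hypotheses that were not tested.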

How the results depend on the processing

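The setting without the 3 arrays apart on component 3 was chosen after the results were seen. Over 216 values of named genes, 172 of them calls, 6877 values under alternatives were computed: 6325 kept direction and side of the threshold, 528 lost the call, 20 gained one and 4 reversed, none of them a call. For 43 list calls, 1229 of 1375 values kept the call and 146 lost it. The reversed values were RLN2 on day 10 at 0.21 without hCG day 10 replicate 1 (range without 1 array -0.76 to 0.21), STAR on day 12 at -0.11 without hCG day 12 replicate 1 (-0.11 to 0.24) and at -0.11 without the 3 arrays. STAR on day 15 reversed too, at -0.03 without hCG day 15 replicate 3 (-0.03 to 0.15). Without 1 array in turn, the counts ran from 1800 to 2535 for the test among the 5 groups, 228 to 577 for day 10, 73 to 290 for day 12, 321 to 774 for day 15, 1375 to 2120 for day 18, 151 to 286 for days 10 to 12, 0 to 4 for days 12 to 15 and 0 to 1 for days 15 to 18. The lists shifted ran from 6 to 11, 4 to 10, 4 to 7, 6 to 9, 1 to 4, 3 to 7 and 5 to 9 in the order of these 7 comparisons. Fits of the 8 arrays alone, with fewer degrees of freedom, gave 172, 7 and 230 on days 10, 12 and 15 and 56 between days 10 and 12, and ended 72 calls of named genes. The upper 50% by mean signal gave 233 on day 12 and 4 lists between days 10 and 12, and array weights gave 254 on day 12. With 1 probe set per gene, fewer were tested, and the counts were 1318 among the groups, 324, 92, 399 and 1160 on days 10 to 18 and 161 between days 10 and 12. Adding a 2-fold threshold, which only removes calls, left 968 among the groups, 246, 342 and 845 on days 10, 15 and 18 and 157 between days 10 and 12. An ordinary F test with unadjusted p gave 8682. A pseudocount of 1 gave 1488 among the groups, 254, 95 and 410 on days 10, 12 and 15, 146 between days 10 and 12 and 2 between days 12 and 15, and ended 41 calls of named genes. Camera with an estimated correlation shifted 0 lists in 6 comparisons (0 on days 10, 12, 15 and 18) and 1 between days 10 and 12. Fry gave 4, 3 and 3 lists on days 10, 12 and 15, and 1, 2 and 0 in the 3 steps. Without the 3 arrays apart on component 3 the counts were 324, 93 and 359 on days 10, 12 and 15, 1 list shifted between days 10 and 12, and 45 calls of named genes and 12 of lists ended. With replicate number as a block the counts were 417, 160, 673, 2002, 250, 0 and 0, and 9 calls of named genes ended. With group means taken out, arrays of different groups show no clear pairing by number, but this cannot exclude one. The 40 pairs with the same number correlate at -0.28 to 0.36 (mean 0.036, 14 pairs over 0.1). The 120 pairs with different numbers correlate at -0.34 to 0.37 (mean -0.012, 24 over 0.1). Of 20 arrays, 7 correlate best with their own number. Except where fewer arrays or probe sets or a stricter rule explain a change, the cause was not tested. Signals under 16, 28.8% to 36.6% of each array, limit what can be seen of weak transcripts.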

Other observations

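On hCG day 18, genes outside the shifted lists also moved. In hypoxia and glycolysis 1 of 20 genes rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.64). Hexokinase genes HK1 (-1.19 ± 0.21, SE, n = 4 per group) and HK2 (-0.91 ± 0.21), PFKFB3 (-0.93 ± 0.22) and the glucose transporter SLC2A1 (-1 ± 0.25) were the ones that fell. For HK1, 1 of 4 probe sets passed the test, and the one that changed least was at -0.16. The other probe set of SLC2A1 was at -0.01. In apoptosis 2 of 21 genes rose and 1 fell (2 and 3 adjusted over the list alone; adjusted p = 0.64). BCL2L11, which promotes cell death, rose by 1.13 ± 0.16, MCL1, which opposes it, by 0.87 ± 0.18 in 1 of its 2 probe sets, and PMAIP1 was at -1.04 ± 0.28. Only 1 of the 6 BCL2L11 probe sets passed, and the lowest was at 0.09. In matrix proteases and inhibitors 2 of 25 rose and 2 fell (5 and 4 adjusted over the list alone; adjusted p = 0.6), with RECK at 1.11 ± 0.25 (1 of its 2 probe sets), MMP16 at 1.53 ± 0.35, MMP10 from a mean signal of 41.7 to 6.59 and MMP1 from 32.7 to 6.22. In IGF and TGF-beta family signalling 4 of 32 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.48), with IGFBP1 at 1.64 ± 0.26, TGFBR3 at 1.17 ± 0.25, IGFBP4 at 0.76 ± 0.16 and ID4 at -1.11 ± 0.19. The day 18 mean of IGFBP1, 15157, lay above the lowest array maximum of 14955, where an increase may not register in full. FSTL3 was at -2.47 ± 0.29, PENK at 0.81 ± 0.20 (1 of its 2 probe sets), ANGPTL4 at 1.57 ± 0.23, KCNJ8 at -1.06 ± 0.14, ACTG2 at -0.75 ± 0.18, PGRMC2 at 0.46 ± 0.13 and TAP1 at -1.39 ± 0.37. SELE, an endothelial adhesion molecule, went from a mean signal of 56 to 9.52. The day 18 signals of MMP10, MMP1 and SELE lay under the 16 added before the logarithm, so the sizes of their decreases are not resolved. After median-centring, ACTG2 and TAP1 did not pass, and after quantile normalisation PENK and PGRMC2 did not.

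The 10 genes that differed most among the 5 groups (all with adjusted p of at most 5.9e-06) held 2 shapes. UNC119, TDRD9, APPL2, DNAJA4, APCDD1, STXBP6 and KCNG3 were higher on hCG day 10 (log2 change 1.12, 1.53, 0.55, 2.01, 0.96, 1.34 and 1.57), and on day 18 stood at -0.71, -1.98, -1.64, 0.17, -0.99, -0.78 and -0.43. CYBRD1 (-0.08, 1.17, 1.85 and 2.26 on days 10, 12, 15 and 18), ANLN, a cytokinesis gene (-0.17, -0.35, -1.31 and -1.88), and SLAIN1 (-0.08, -0.92, -1.44 and -1.85) moved further from the baseline with each collection day.

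The 11 lists that shifted in no comparison were luteal peptide hormones and their partners, prostaglandin synthesis and receptors, steroid hormone receptors and partners, angiogenic factors, matrix proteases and inhibitors, neutrophils, erythrocytes, follicular, theca and other ovarian cells, hypoxia and glycolysis, endoplasmic reticulum stress, and IGF and TGF-beta family signalling. Their smallest camera adjusted p was 0.055.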
